A study of Homo sapiens with 6 samples.

How the data were processed

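RNA was measured in H460 cells, a human non-small cell lung cancer line, after transfection with a pool of siRNAs against FGF13 (siFGF13) or with a non-targeting control pool (siC), both at 20 nM per the labels' protocols. The series held 6 libraries in 2 groups of 3, and each library was placed in its group by its sample title. Per the labels' protocols, total RNA came from frozen cell pellets and libraries were made with the TruSeq RNA v2 kit, a kit designed to select polyadenylated RNA that does not mark the strand. The siRNA sequences and the time between transfection and harvest are not given in the sources used here.

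The deposited count table holds whole-number read counts per gene symbol for the 6 libraries, made by the authors. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq 1.18.0, and the genome build hg19. Counting options such as the strand setting and the treatment of reads that fit several genes are not given in the sources used here. Genes with near-identical copies and overlapping or antisense genes are therefore uncertain, because their reads cannot be told apart. The second deposited table holds a normalized signal, the same counts divided by 1 size factor per library. Dividing out that factor gave whole reads for 100% of values within a tolerance of 0.01, and 100% of them equalled the count table. As the recovered reads were identical to the count table, the test on them had to call the same 1182 genes higher and 1446 genes lower. The tables name genes by symbol and give no positions, so no coordinates are printed.

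The count table listed 23368 symbols, of which 5365 had no reads in the 6 libraries. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13072 genes and set aside 10296. Libraries were scaled by TMM, and groups were compared with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust dispersion) with group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as passing. Fold changes are siFGF13 over siC. Standard errors of log2 fold changes were derived from the F statistic, and levels are TMM-normalized counts scaled to library size (CPM), given as mean ± SD over 3 libraries.

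Before the data were examined, 34 gene lists, the tests, the alternatives and a rule for the genes to be named were fixed. The rule took FGF13 and the 8 largest increases and 8 largest decreases among genes that passed, reached a mean of 5 CPM in the higher group and had no overlap between the groups. It added up to 4 members of each list that passed camera, with up to 2 members that passed in the other direction, and up to 2 examples from each other list, taken by smallest adjusted p. A fixed set of genes was also named whatever their values, among them CDKN1A, MDM2, GDF15, MYC, UBTF, POLR1A, NCL, FBL, NOP56, HSPA5, DDIT3, ATF4, ATF3, HMOX1, HSPA1A, FGF11, FGF12, FGF14, FGF2 and FGFR1. The text gives a selection of the genes and lists. Other genes are said to have been chosen after their values were seen. Older symbols were matched through the synonyms of the RefSeq gene table.

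The 28 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Markers of other cell types were summed per library and compared with a two-sided exact permutation test, for which 3 against 3 cannot give a p below 0.1. None of the 13 messenger RNAs of the mitochondrial genome on the list of that name was found by symbol, so that list is not analysed here.

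Library totals ran from 13151632 to 17685029 counts, so a gene without reads in a library lay below 0.17 to 0.228 CPM, taking 3 counts as the limit. This limit covers counting error only. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.02 to 35.7 within groups over genes with at least 20 counts in the pair, so no library was treated as a copy of another. The labels do not say whether the replicates were separate cultures, and p-values measure only the spread between these libraries, which may be technical.

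Same-numbered libraries deviated together from their group means, with correlations across genes of 0.32 for replicate 1, 0.20 for replicate 2 and 0.24 for replicate 3. These correlations, together with the sample numbers shared in the column names, were taken to pair the libraries, and a fit with the replicate number as a block is printed where it changed a call or moved a count by more than 1.5 times. The other alternatives were RLE and upper-quartile scaling, no filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, edgeR's glmTreat against a 1.2-fold change, and each library left out in turn. Both replicate 1 libraries left out, and the block with a correction for transcript length and GC content, were added after the data were seen. So was fry with the block. The block leaves fewer residual degrees of freedom, which by itself can raise fry p-values. Length, GC content and 3' untranslated regions came from GENCODE v29 transcripts and covered 12550 of the 13072 tested genes (96.0%) for length and GC.

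The test was checked on simulated counts for 13042 genes, of which 200 were changed, with the means, library sizes and spread of the siFGF13 and siC libraries. The edgeR test recovered 58.2% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 93.9% of those changed 4-fold, with 16 false calls. In the same simulation a further set of 40 genes, shifted 1.3-fold, was called by camera with the preset and the estimated correlation. An unshifted set of 40 genes was called by neither. The simulated genes varied independently, with an estimated correlation of -0.00622 in the shifted set, against -0.0476 to 0.860 in the lists tested. The simulation therefore cannot tell which correlation setting suits these lists. In the shifted set the camera p was 2.68e-28 with the preset correlation and 2e-04 with the estimated one, although the estimate lay below the preset. A weaker camera result with an estimated correlation therefore need not come from correlation between the genes. Figures were drawn and the motif and gene family tests were run in Python 3.11.15 with numpy 2.4.6.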

Results

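H460 cells were compared after transfection with siRNAs against FGF13 or with control siRNAs, to find which transcripts differed when this gene was depleted. FGF13 belongs to the intracellular fibroblast growth factors, which bind sodium channels and microtubules and do not signal as secreted ligands. The control libraries held 13752128, 16863566 and 13151632 counts, and the siFGF13 libraries held 16096859, 16872605 and 17685029 counts for replicates 1, 2 and 3. The most abundant gene, EEF1A1, took 0.736% to 1.05% of the counts, and the 10 most abundant genes took 4.91% to 5.23%. In a principal component analysis of log2 CPM, the first component held 57.4% of the variance and separated the groups. The second held 22.5%, and on it the replicate 1 libraries of both groups (20.9 for siC and 19.3 for siFGF13) stood apart from the other 4, which lay between -14.8 and -4.13.

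FGF13 itself was lower in each siFGF13 library than in each siC library. It had 837, 1445 and 923 counts in siC replicates 1, 2 and 3, and 192, 383 and 370 counts in siFGF13 replicates 1, 2 and 3. Its level fell from 72.7 ± 11.4 CPM to 18.4 ± 5.59 CPM (n = 3 each), a 3.95-fold reduction (log2 fold change -1.98 ± 0.21 SE, edgeR adjusted p = 0.00193). The log2 ratio within replicates 1, 2 and 3 was -2.38, -1.92 and -1.75. Of the related intracellular factors, FGF11 (1.23 ± 0.247 against 1.11 ± 0.311 CPM, adjusted p = 0.768) and FGF14 (3.72 ± 0.570 against 3.38 ± 0.454 CPM, adjusted p = 0.642) did not pass the edgeR test. FGF12 had too few reads to be tested, with 4, 8 and 3 counts in siC and 3, 9 and 1 counts in siFGF13.

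Many genes differed between the groups, mostly by modest amounts. The stress response genes DDIT3, ASNS and SESN2 and the cytokine gene IL6 fell, and the chaperone genes HSPA8 and HSPA1A rose. Of the 28 gene lists tested, camera called 5 lower, with 33 of 38 ATF4 targets, 14 of 25 NF-kB targets, 9 of 29 matrix genes, 9 of 33 endoplasmic reticulum genes and 12 of 38 autophagy and lysosome genes lower, and 13 higher. Camera called 0 of them with an estimated correlation (adjusted p = 0.230 to 0.588 with an estimated correlation; 1 list at an unadjusted p under 0.05), and fry called 14 of these 18, or 2 with the replicate block. Of 13072 genes tested with edgeR, 1182 were higher and 1446 lower at an adjusted p under 0.05, 20.1% in all. Of these, 55 of the higher genes and 194 of the lower genes reached 2-fold. The groups did not overlap for 5912 genes (45.2%, against 10% by chance). With the replicate number as a block, 1821 genes were higher and 2244 lower, and the 2628 genes called without the block were all among them. The counts depended on which library was left out. Leaving out siFGF13 replicate 1 left 149 higher and 275 lower, and siFGF13 replicate 3 260 and 403. Leaving out siFGF13 replicate 2 left 450 and 621, and siC replicate 3 408 and 783. Without siC replicate 1, the control library farthest from its group, 1407 genes were higher and 1662 lower. With both replicate 1 libraries left out, 1460 were higher and 1776 lower. The small counts without siFGF13 replicate 1 alone therefore do not show that the calls rest on that library.

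**Figure D1:**
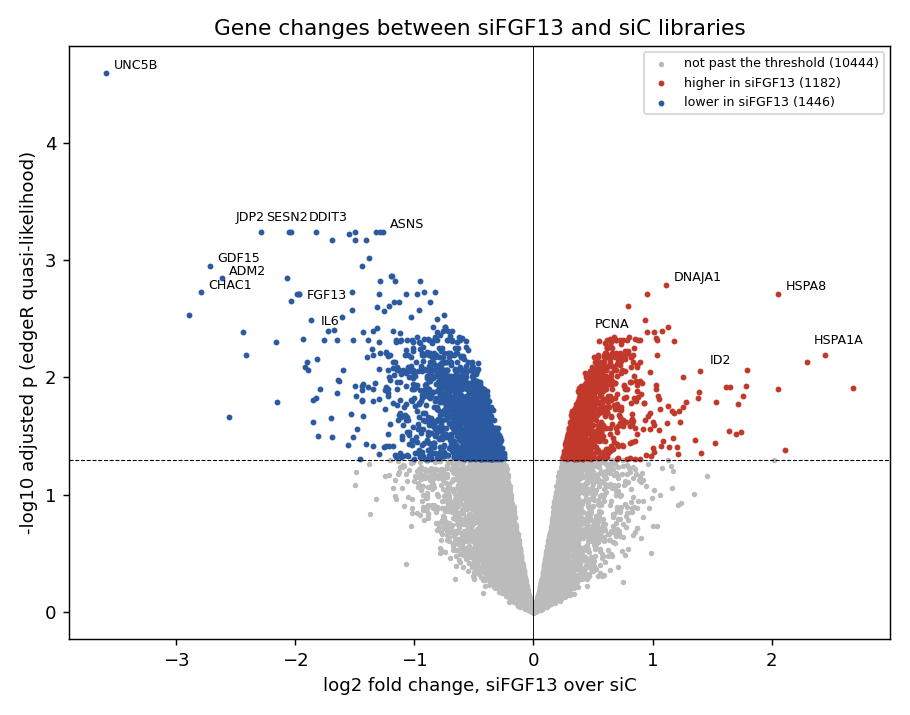
Each point is 1 of the 13072 tested genes, with its log2 fold change (siFGF13 over siC) on the x axis and -log10 of its edgeR adjusted p on the y axis. The dashed line marks an adjusted p of 0.05, red points are the 1182 higher genes and blue points the 1446 lower genes, with UNC5B, FGF13, stress response genes and heat shock genes among those farthest out.

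UNC5B, a netrin receptor, showed the largest reduction of the genes the naming rule allowed. It fell from 48.0 ± 5.55 to 4.01 ± 0.781 CPM (n = 3 each; log2 fold change -3.59 ± 0.16, edgeR adjusted p = 2.54e-05). The next largest decreases among genes that reached a mean of 5 CPM were of CHAC1, which degrades glutathione (6.93-fold), the stress cytokine GDF15 (6.57-fold), the peptide hormone ADM2 (6.14-fold), the transcription factor JDP2 (4.90-fold), the glucocorticoid-induced gene TSC22D3 (4.19-fold), AKNA (4.15-fold) and the NKG2D ligand ULBP1 (4.10-fold). Their adjusted p-values lay between 0.000575 and 0.00223. The largest increases among genes that reached a mean of 5 CPM, which left out HSPA6, were of the HSP70 genes HSPA1A (5.46-fold), HSPA1B (4.92-fold) and HSPA8 (4.16-fold), together with IGFN1 (4.32-fold), the semaphorin co-receptor NRP1 (3.30-fold), the helix-loop-helix inhibitors ID3 (3.07-fold) and ID2 (2.64-fold), and the transcription factor GATA2 (2.60-fold). HSPA1A and HSPA1B are near-identical copies, so the share of reads between them is uncertain. The calls of NRP1, ID3, ID2 and GATA2 ended without siC replicate 1 (adjusted p = 0.132, 0.153, 0.0812 and 0.119), and that of NRP1 also without siC replicate 3 (0.0582). IGFN1 kept its call in 1 of the 6 fits with a library left out, and lost it without siC replicates 1, 2 and 3 (0.244, 0.157 and 0.0950) and siFGF13 replicates 1 and 3 (0.116 and 0.0690).

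Of 38 tested targets of the transcription factors ATF4 and CHOP, the integrated stress response, 33 were lower and none was higher, and 37 were lower when adjusted over the list alone. The list passed camera (adjusted p = 7.47e-21) but not with an estimated correlation (adjusted p = 0.230 with an estimated correlation). The mean log2 fold change was -1.07 and the median -0.89, with means from -1.24 in the replicate 1 pair to -0.93 in the replicate 3 pair. DDIT3, which encodes CHOP, fell from 67.5 ± 13.2 to 19.0 ± 0.599 CPM (log2 fold change -1.83 ± 0.14, edgeR adjusted p = 0.000575). Asparagine synthetase ASNS fell from 229 ± 17.7 to 95.1 ± 2.44 CPM (-1.27 ± 0.09, adjusted p = 0.000575), and SESN2, a sestrin that restrains mTORC1, from 75.5 ± 9.62 to 18.4 ± 3.74 CPM (-2.03 ± 0.16, adjusted p = 0.000575). ATF3 fell 3.23-fold (adjusted p = 0.000675). The transcript of ATF4, which is regulated mainly in translation, stood at 449 ± 39.2 CPM in siC and 450 ± 20.6 CPM in siFGF13 (log2 fold change 0.00 ± 0.10, adjusted p = 0.988). Between 24 (without siFGF13 replicate 1) and 33 members were lower with each library left out in turn.

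Chaperones and targets of the endoplasmic reticulum stress sensors IRE1 and ATF6 were lower as a list in camera (adjusted p = 0.00462) but not in fry (0.152, or 0.123 with the block). The call was lost with an estimated correlation (adjusted p = 0.559 with an estimated correlation). Of 33 tested members, 9 were lower and 1 higher (13 and 1 adjusted over the list alone, 14 and 1 with the replicate block). XBP1, the transcription factor activated by IRE1, fell from 194 ± 59.6 to 84.1 ± 4.08 CPM (log2 fold change -1.20 ± 0.18, edgeR adjusted p = 0.00648). ERN1, which encodes IRE1, fell 1.75-fold (adjusted p = 0.00806) and HERPUD1, a factor of protein degradation at this organelle, 1.73-fold (adjusted p = 0.00861). HSPA5, the main chaperone of the organelle, did not pass (2810 ± 616 against 2510 ± 193 CPM, adjusted p = 0.468), while SEC61B, a subunit of the translocation channel, was 1.36-fold higher (adjusted p = 0.0125). The list mean was -0.27. Without siC replicate 1 the mean was -0.15, and 4 members were lower without siFGF13 replicate 1 or 3, 5 without siFGF13 replicate 2, 6 without siC replicate 3 and 15 without siC replicate 2. SEC61B lost its call without siFGF13 replicate 1 (0.0558) and replicate 3 (0.0604). Autophagy and lysosome genes were also lower as a list, with 12 of 38 tested members lower, none higher, and a median of -0.28 (14 lower and 1 higher adjusted over the list alone, 16 and 2 with the block). The autophagy and lysosome list passed camera (adjusted p = 0.0276) but neither with an estimated correlation (adjusted p = 0.427 with an estimated correlation) nor in fry with the block (0.119). GABARAPL1, which coats autophagosomes, fell 1.70-fold (adjusted p = 0.0104). Between 1 (without siFGF13 replicate 1) and 16 (without siC replicate 1) of the autophagy and lysosome genes were lower with a library left out, including 2 without siFGF13 replicate 3 and 4 without siFGF13 replicate 2.

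Of 31 tested cytosolic chaperones and other genes driven by HSF1, 21 were higher and none lower (25 and 1 adjusted over the list alone), with a mean log2 fold change of 0.68 and a median of 0.47. This heat shock list passed camera (adjusted p = 2.07e-11) but neither with an estimated correlation (adjusted p = 0.427 with an estimated correlation) nor in fry with the block (0.0894). HSPA8, the constitutive HSP70, rose from 829 ± 255 to 3448 ± 292 CPM (2.06 ± 0.22, edgeR adjusted p = 0.00193) and the inducible HSPA1A from 12.9 ± 7.16 to 71.3 ± 16.9 CPM (2.45 ± 0.37, adjusted p = 0.00641). The co-chaperones DNAJA1 and CHORDC1 rose 2.17-fold (adjusted p = 0.00163) and 1.47-fold (adjusted p = 0.00492). Proteasome subunits had 7 of 33 tested members higher, none lower and a median of 0.22 (7 adjusted over the list alone, 11 with the block), and PSMB2 rose 1.53-fold (adjusted p = 0.00481). The proteasome list passed camera (adjusted p = 9.91e-08) but neither with an estimated correlation (adjusted p = 0.460 with an estimated correlation) nor in fry with the block (0.119). With single libraries left out, the heat shock count dropped to 9 without siFGF13 replicate 1, 11 without siFGF13 replicate 3, and 14 without siFGF13 replicate 2 or siC replicate 3. The proteasome count dropped to 1 without siFGF13 replicate 1 or 3 and to 3 without siFGF13 replicate 2 or siC replicate 3.

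**Figure D2:**
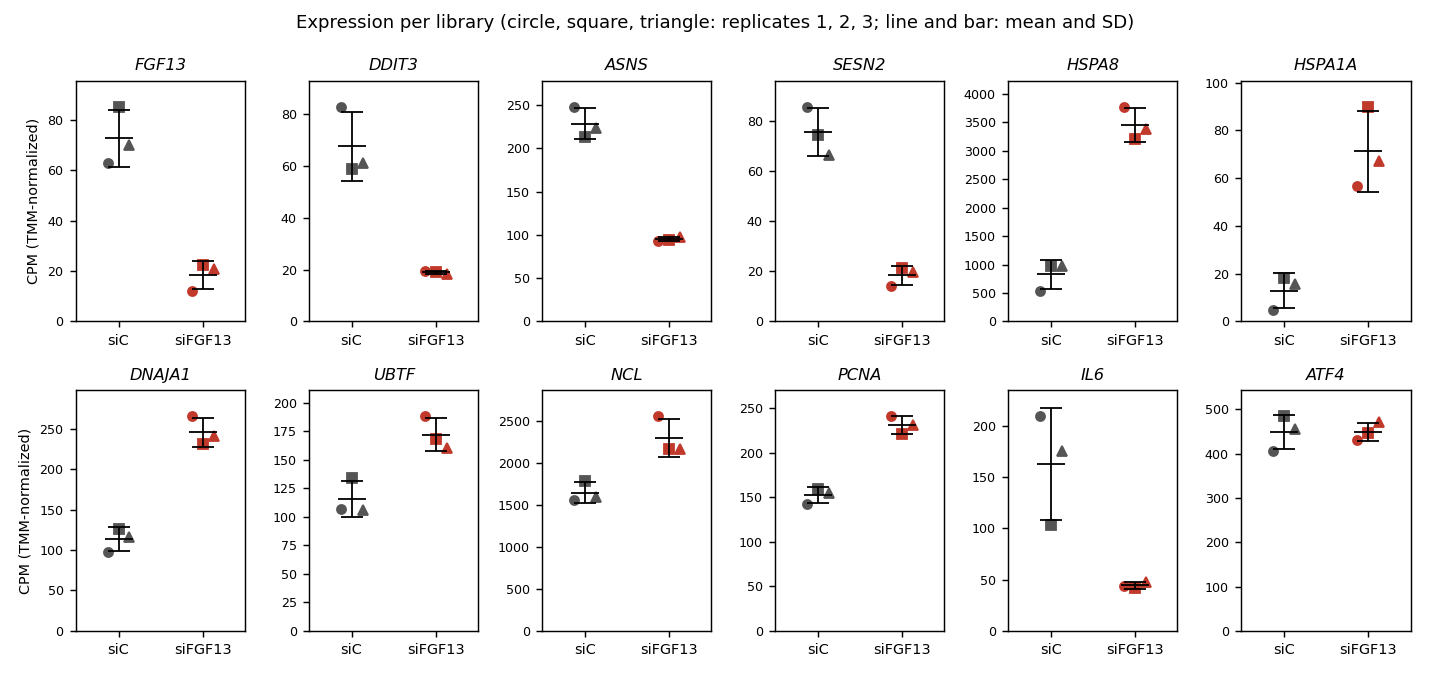
TMM-normalized CPM of 12 named genes in each library, on linear axes that start at 0, with circles, squares and triangles for replicates 1, 2 and 3, and a line and bar for the mean and SD of the 3 libraries. FGF13, DDIT3, ASNS, SESN2 and IL6 lay lower, and HSPA8, HSPA1A, DNAJA1, UBTF, NCL and PCNA higher, in each siFGF13 library than in each siC library, while the ATF4 values overlapped.

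Of 71 tested factors that build ribosomes in the nucleolus, 35 were higher, none lower and 36 did not pass (47 higher adjusted over the list alone), with a median log2 fold change of 0.35 and means of 0.52, 0.18 and 0.34 within replicates 1, 2 and 3. The list passed camera (adjusted p = 1.01e-14) but neither with an estimated correlation (adjusted p = 0.427 with an estimated correlation) nor in fry with the block (0.119). The rRNA processing factor IMP3 rose from 28.5 ± 3.78 to 49.4 ± 4.15 CPM (1.73-fold, edgeR adjusted p = 0.00595), NOP16 rose 1.67-fold (adjusted p = 0.00723), RRP1B 1.53-fold (adjusted p = 0.00670) and UTP14A 1.52-fold (adjusted p = 0.00671). Nucleolin, NCL, was 1.40-fold higher (adjusted p = 0.0208). Fibrillarin, FBL, did not pass (log2 fold change 0.20, adjusted p = 0.164), nor did NOP56 (0.35, adjusted p = 0.0743), which passed with the replicate block (adjusted p = 0.0189). NCL lost its call without siC replicate 3 (0.0669) and without siFGF13 replicates 1, 2 and 3 (0.0995, 0.0593 and 0.0673). The count of higher members was 6 without siFGF13 replicate 1, 8 without siFGF13 replicate 3 and 13 without siC replicate 3. The list mean moved less. It was 0.35 with all libraries, and ran from 0.30 (without siFGF13 replicate 1) to 0.39 (without siC replicate 2) with 1 library left out.

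RNA polymerase I and its factors, which transcribe rRNA, passed camera as a higher list (adjusted p = 0.00194). They passed neither with an estimated correlation (adjusted p = 0.427 with an estimated correlation) nor in fry with the block (0.123). Of 16 tested members, 6 were higher and none lower (9 adjusted over the list alone), with a median of 0.28. UBTF, which organises the rRNA genes for transcription, rose from 116 ± 15.8 to 172 ± 14.5 CPM (1.49-fold, edgeR adjusted p = 0.0128), and POLR1A, the largest polymerase I subunit, was 1.35-fold higher (adjusted p = 0.0400). Without siFGF13 replicate 1 the UBTF call ended (0.0662), as did that of POLR1A without siC replicates 1 and 3 (0.0668 and 0.118) and without siFGF13 replicates 1, 2 and 3 (0.142, 0.115 and 0.0692). The number of higher members was 1 without siC replicate 3 or siFGF13 replicate 2, and 2 without siFGF13 replicate 3. It was 0 in edgeR without siFGF13 replicate 1 (6 at an unadjusted p under 0.05).

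Of 76 tested cytosolic ribosomal protein genes, 4 were higher, none lower and 72 did not pass (1 higher adjusted over the list alone, 8 with the block), with a median log2 fold change of 0.18, and fry did not call this list (adjusted p = 0.145, or 0.176 with the block). RPS26, part of the small subunit, rose 1.57-fold (205 ± 14.1 to 322 ± 17.0 CPM, edgeR adjusted p = 0.00495), and as many ribosomal protein genes have processed copies in the genome, their counts carry some uncertainty. MYC-activated genes outside ribosome production had 19 of 44 tested members higher and none lower (21 adjusted over the list alone), although MYC itself did not pass (321 ± 57.6 against 367 ± 26.1 CPM, adjusted p = 0.319). The mitochondrial chaperonin HSPE1 from that list, which is also on the heat shock list, rose (log2 fold change 0.59, adjusted p = 0.00805). Mitochondrial ribosomal proteins had 19 of 75 tested members higher and none lower (26 adjusted over the list alone, 34 with the block), among them MRPL19 (1.41-fold, adjusted p = 0.00812). Nuclear-encoded respiratory chain and ATP synthase subunits had 11 of 62 higher and 1 lower, in number alike adjusted over the list alone. ATP5G1, a subunit of the ATP synthase ring, was higher (log2 fold change 0.38, adjusted p = 0.0122) and COX6A1, of cytochrome oxidase, 1.24-fold lower (adjusted p = 0.0383). These 4 lists passed camera (adjusted p = 3.80e-08, 1.91e-09, 3.54e-10 and 0.000157 in the order given), and none passed with an estimated correlation (adjusted p = 0.559, 0.427, 0.427 and 0.495 with an estimated correlation) or in fry with the block (0.176, 0.119, 0.119 and 0.0894). The ribosomal protein mean of 0.20 was 0.10 without siC replicate 1, where 8 members were higher, and 2 were higher without siC replicate 3 and 1 without siFGF13 replicate 1, 2 or 3. Without siC replicate 3 and siFGF13 replicates 1, 2 and 3, higher MYC-activated genes numbered 4, 1, 6 and 3, and mitochondrial ribosomal proteins 10, 2, 9 and 2. Higher respiratory chain genes numbered 2 without siC replicate 3 or siFGF13 replicate 2 and 0 in edgeR without siFGF13 replicate 1 or 3 (17 and 11 at an unadjusted p under 0.05). COX6A1 lost its call without siC replicate 3 (0.0787) and siFGF13 replicates 1, 2 and 3 (0.143, 0.108 and 0.117), and ATP5G1 without siFGF13 replicates 1 and 3 (0.0540 and 0.0641).

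GDF15, a cytokine of cell stress and 1 of the largest decreases, fell from 66.5 ± 9.36 to 10.1 ± 3.87 CPM (log2 fold change -2.72 ± 0.25, edgeR adjusted p = 0.00112). The cell cycle inhibitor CDKN1A (30.6 ± 8.69 against 32.7 ± 2.84 CPM, adjusted p = 0.736) and the ubiquitin ligase MDM2 (log2 fold change -0.09 ± 0.09 SE, adjusted p = 0.515) did not pass.

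Of 50 tested DNA replication genes on the S-phase list, 18 were higher, none lower and 32 did not pass (23 higher adjusted over the list alone), with a median of 0.25. The list passed camera (adjusted p = 1.00e-08) but neither with an estimated correlation (adjusted p = 0.427 with an estimated correlation) nor in fry with the block (0.0881). FEN1, a nuclease of lagging strand synthesis, rose from 91.1 ± 4.53 to 142 ± 9.62 CPM (1.56-fold, edgeR adjusted p = 0.00471), the cyclin CCNE2 rose 2.05-fold (adjusted p = 0.00481), CDC6, which loads the replicative helicase, 1.60-fold (adjusted p = 0.00670) and the sliding clamp PCNA 1.52-fold (adjusted p = 0.00505). Mitotic genes had 12 of 50 tested members higher and 2 lower (13 and 2 adjusted over the list alone) and a median of 0.09. The mitotic list passed camera (adjusted p = 0.0189) but neither with an estimated correlation (adjusted p = 0.450 with an estimated correlation) nor in fry with the block (0.101). The mitotic activator CDC20 was 1.52-fold higher (adjusted p = 0.0123), whereas the kinetochore protein NDC80 (adjusted p = 0.0172) and the phosphatase CDC25C (adjusted p = 0.0441) were 1.35-fold and 1.36-fold lower. Without siC replicate 2 the mitotic list no longer passed (0.0544). CDC20 lost its call without siFGF13 replicate 1 (0.0604), NDC80 without siFGF13 replicates 1 and 3 (0.0752 and 0.0664), and CDC25C without siC replicate 3 (0.132) and siFGF13 replicates 1, 2 and 3 (0.146, 0.0850 and 0.108). The S-phase count was 7 without siFGF13 replicate 1 and 10 without siFGF13 replicate 3, and the mitotic count of higher genes was 0 in edgeR without siFGF13 replicate 1 (14 at an unadjusted p under 0.05), 1 without siFGF13 replicate 3, 2 without siC replicate 3 and 3 without siFGF13 replicate 2.

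Tubulins and microtubule-binding proteins had 9 of 29 tested members higher and 1 lower (12 and 2 adjusted over the list alone, 11 and 2 with the block), with a median of 0.17. The list passed camera (adjusted p = 0.00462) but neither with an estimated correlation (adjusted p = 0.495 with an estimated correlation) nor in fry (0.0753, or 0.123 with the block). The alpha tubulins TUBA1C and TUBA4A rose 1.70-fold and 1.49-fold (edgeR adjusted p = 0.00696 and 0.00809), and the microtubule-associated kinase DCLK1 was 1.76-fold lower (adjusted p = 0.0114). Tubulin genes share long stretches of sequence, so reads may have been split between them. Replication-dependent histones, most of whose messages lack a poly(A) tail, had 1 of 6 tested members higher (2 adjusted over the list alone, 2 with the block). This was HIST1H2BK, at 27.1 ± 5.44 CPM in siC against 57.4 ± 1.06 CPM in siFGF13 (edgeR adjusted p = 0.00401). Whether the histone reads came from messages with or without a tail was not tested. The histone list passed camera (adjusted p = 0.00194) but neither with an estimated correlation (adjusted p = 0.427 with an estimated correlation) nor in fry with the block (0.119). The histones were listed as a sign of RNA selection and quality, and their mean log2 change was 0.69. A difference in either between the groups was therefore not excluded for the higher lists. Only 6 of the 26 listed histones could be tested, and HIST1H3H among them stood at 0.365 CPM in siC and 0.726 CPM in siFGF13. The S-phase list was also higher, so the histones cannot separate RNA selection or quality from a change in the cell cycle. The microtubule mean of 0.19 was 0.11 without siC replicate 1, and its count of higher members was 2 without siFGF13 replicate 1, 4 without siFGF13 replicate 3 and 5 without siFGF13 replicate 2 or siC replicate 3. DCLK1 lost its call without siFGF13 replicate 1 (0.0648). Apoptosis regulators had 5 of 32 higher and 4 lower (6 and 7 adjusted over the list alone, 6 and 8 with the block), and did not pass camera (adjusted p = 0.778). Their counts were 2 and 3 without siC replicate 3, 3 and 6 without siC replicate 2, and 0 higher in edgeR with 1, 3 and 2 lower without siFGF13 replicates 1, 2 and 3 (5, 6 and 5 higher at an unadjusted p under 0.05). In that list the BH3-only gene PMAIP1 fell 1.98-fold (adjusted p = 0.00193).

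Of 25 tested NF-kB targets and inflammatory cytokines, 14 were lower, none higher and 11 did not pass (15 lower adjusted over the list alone), with a median log2 fold change of -0.51. The list passed camera (adjusted p = 0.000118) but not with an estimated correlation (adjusted p = 0.427 with an estimated correlation). Interleukin 6, IL6, fell from 163 ± 54.5 to 44.6 ± 3.20 CPM (-1.87 ± 0.22, edgeR adjusted p = 0.00324), the prostaglandin synthase PTGS2 fell 3.82-fold (adjusted p = 0.00467) and IL1A 3.38-fold (adjusted p = 0.00481). Interleukin 8, listed as IL8, was 3.77-fold lower (adjusted p = 0.00807), a call that ended without siC replicate 1 (0.105) and siFGF13 replicate 1 (0.0520). With libraries left out in turn, 4 members were lower without siFGF13 replicate 1, 7 without siFGF13 replicate 3, and 8 without siFGF13 replicate 2 or siC replicate 3.

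Mesenchymal and matrix genes were lower as a list, with 9 of 29 tested members lower and 1 higher (10 and 1 adjusted over the list alone, 14 and 1 with the block) and a median of -0.35. The list passed camera (adjusted p = 0.00217) but neither with an estimated correlation (adjusted p = 0.442 with an estimated correlation) nor in fry with the block (0.0598). The matricellular protein CTGF fell from 178 ± 63.3 to 56.6 ± 7.75 CPM (-1.65 ± 0.22, edgeR adjusted p = 0.00481), the fibronectin receptor subunit ITGA5 fell 1.91-fold (adjusted p = 0.00641) and TGFB2 1.84-fold (adjusted p = 0.00803). SNAI1, a transcription factor that represses epithelial genes, was 1.76-fold higher (adjusted p = 0.0164), a call that ended without siC replicate 3 (0.0514) and siFGF13 replicates 1 and 3 (0.0723 and 0.0560). Summed fibroblast markers stood at 122 ± 25.9 CPM in siC and 70.0 ± 2.78 CPM in siFGF13 (n = 3 each, two-sided exact permutation p = 0.1, the smallest possible), and COL3A1 made up 61.4% of the sum. Of the matrix list, 4 members were lower without siFGF13 replicate 1 or 2, 5 without siFGF13 replicate 3 and 6 without siC replicate 3.

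Early response genes and feedback regulators of the ERK pathway had 3 of 27 tested members higher and 7 lower, in number alike adjusted over the list alone (3 and 12 with the block), and did not pass camera (adjusted p = 0.171). Their mean log2 change was -0.10, but 0.08 with no filter, -0.05 without siFGF13 replicate 2, near 0 (-0.00194) without siC replicate 3 and -0.18 without siC replicate 1. The phosphatase DUSP1 fell 2.26-fold (edgeR adjusted p = 0.00225) and the receptor EPHA2 1.63-fold (adjusted p = 0.00445). The ERK list passed camera without siC replicate 1 (0.0217), and 3 of its members were lower without siC replicate 3 or any 1 siFGF13 replicate. Its higher members numbered 1 without siC replicate 1 or 3 and 0 in edgeR without siFGF13 replicate 1 (3 at an unadjusted p under 0.05). Epithelial junction genes had 2 of 17 higher and 3 lower, in number alike adjusted over the list alone (2 and 6 with the block), and did not pass camera (adjusted p = 0.160), though they did without siC replicate 1 (0.0483), and 1 member was higher without any of the other 5 libraries in turn. The clathrin adaptor AP1M2 rose 1.72-fold (adjusted p = 0.00481) and the claudin CLDN1 fell 2.01-fold (adjusted p = 0.00894). Fibroblast growth factors, their receptors and partners had 2 of 11 tested members lower and none higher (2 adjusted over the list alone, 4 with the block; camera adjusted p = 0.213). FGFR1 was 1.42-fold lower (60.7 ± 7.86 against 42.6 ± 1.14 CPM, adjusted p = 0.0138), a call that ended without siFGF13 replicates 1 and 3 (0.0654 and 0.0629), and FGF2 did not pass (50.5 ± 4.35 against 52.3 ± 4.63 CPM, adjusted p = 0.731). Of that list, 1 member was lower without siFGF13 replicate 2 and 0 in edgeR without siFGF13 replicates 1 and 3 (2 and 3 at an unadjusted p under 0.05).

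**Figure D3:**
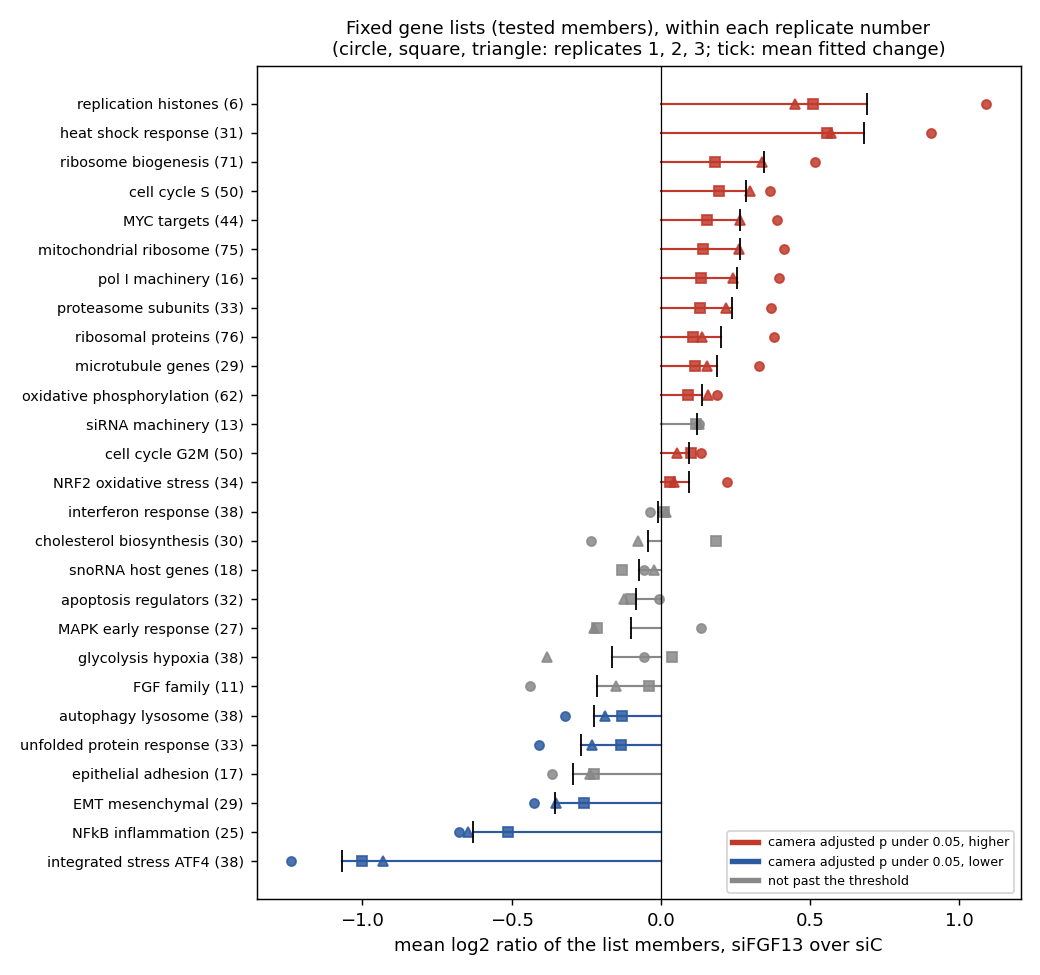
Mean log2 ratio (siFGF13 over siC) of the tested members of 27 of the 28 tested lists within replicates 1 (circles), 2 (squares) and 3 (triangles). A tick marks the mean fitted change, and the number of tested members is in brackets. The ATF4 list lay lowest, at -1.24 to -0.93, and the replicate 1 pair lay farthest from 0 in the 18 lists that passed camera.

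Antioxidant genes driven by NRF2 barely passed camera (adjusted p = 0.0476), with 3 of 34 tested members higher and 1 lower (2 and 1 adjusted over the list alone, 5 and 3 with the block). The list did not pass with an estimated correlation (adjusted p = 0.588 with an estimated correlation), with fry (0.212), with the replicate block (0.0785), with upper-quartile scaling (0.0539), with the 5 CPM filter (0.0768), or without siC replicate 1 (0.406) or siFGF13 replicate 2 (0.0786). Its call also ended without both replicate 1 libraries (0.378) and with the block and length and GC correction (0.0889). Its mean of 0.09 was 0.05 without siC replicate 1 and 0.04 without both replicate 1 libraries, but 0.19 with no filter. Its higher members numbered 1 without siFGF13 replicate 1, and lower ones 0 in edgeR without siFGF13 replicates 1, 2 and 3 (3, 1 and 1 at an unadjusted p under 0.05). Heme oxygenase, HMOX1, was 2.06-fold higher (28.0 ± 3.33 against 58.0 ± 19.8 CPM, edgeR adjusted p = 0.0144), a call that ended without siC replicate 1 (0.123). Glycolytic and hypoxia-induced genes had 1 of 38 higher and 6 lower, in number alike adjusted over the list alone (2 and 9 with the block). Their median (0.02) and mean (-0.16, but -0.24 without siC replicate 1, -0.11 without siFGF13 replicate 1 and near 0 without siC replicate 3) differed in sign, as did camera (higher) and fry (lower), and camera did not pass (adjusted p = 0.994). Lower members numbered 3, 2, 3 and 3 without siC replicate 3 and siFGF13 replicates 1, 2 and 3, where higher ones numbered 0 in edgeR (6, 2, 2 and 1 at an unadjusted p under 0.05). Without siC replicate 1, 2 were higher, and without siC replicate 2, 0 in edgeR (7 at an unadjusted p under 0.05). The glucose transporter SLC2A3 fell from 389 ± 81.3 to 121 ± 30.8 CPM (-1.68 ± 0.21, adjusted p = 0.00394) and the angiogenic factor VEGFA, which is also on the ATF4 list, fell 1.93-fold (adjusted p = 0.00512).

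Sterol synthesis genes (3 of 30 higher and 2 lower, 4 and 6 with the block, camera adjusted p = 0.715) did not pass as a list, and their counts were the same in number adjusted over the list alone. Without siFGF13 replicates 1 and 3 edgeR called 0 sterol genes (5 and 3 higher, 2 and 2 lower at an unadjusted p under 0.05). The counts were 1 and 1 without siFGF13 replicate 2, 3 and 4 without siC replicate 2, and 3 and 0 without siC replicate 3 (6 lower at an unadjusted p under 0.05). NSDHL, an enzyme of this pathway, was 1.35-fold higher (edgeR adjusted p = 0.0116) but not without siFGF13 replicates 1 and 3 (0.0574 and 0.0538). Interferon-stimulated genes (3 of 38 higher and 4 lower, also adjusted over the list alone, camera adjusted p = 0.757) did not pass either, with a median of 0.08 and a mean near 0 whose sign depended on the setting. Without siC replicate 3 or siFGF13 replicate 1, 2 or 3, edgeR called 0 of them (5, 5, 4 and 3 higher and 7, 5, 6 and 6 lower at an unadjusted p under 0.05), and without siC replicate 2, 1 was higher. Their member PARP14 was 1.32-fold lower (adjusted p = 0.0229), a call that ended without siC replicate 3 (0.0627) and siFGF13 replicates 1, 2 and 3 (0.0977, 0.0653 and 0.0835). RNA interference genes had 3 of 13 higher and 1 lower (4 and 1 adjusted over the list alone) and an adjusted p of 0.0527, which passed with fry (0.0295), the block (0.0417), upper-quartile scaling (0.0495), no filter (0.0381), limma-voom (0.0436), without siC replicate 1 (0.0200) and without siFGF13 replicate 3 (0.0464). It also passed without both replicate 1 libraries (0.0236) and with the block and length and GC correction (0.0141), but not with an estimated correlation (adjusted p = 0.427 with an estimated correlation). Without siC replicate 3 or siFGF13 replicate 1, 2 or 3, edgeR called 0 members higher (4, 3, 5 and 4 at an unadjusted p under 0.05). The Argonaute gene EIF2C4 was 1.53-fold lower (adjusted p = 0.0111), but not without siFGF13 replicate 1 (0.0554). Hosts of small nucleolar RNAs had 2 of 18 lower and none higher, also adjusted over the list alone (4 and 1 with the block, camera adjusted p = 0.544). Of these, GAS5 was 1.42-fold lower (adjusted p = 0.00862), a call that ended without siFGF13 replicate 1 (0.0530), where edgeR called 0 of these hosts lower (4 at an unadjusted p under 0.05). Of the hosts, 1 was lower without siC replicate 3 or siFGF13 replicate 2 or 3, and 4 without siC replicate 1.

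Markers of other cell types were low apart from those of fibroblasts. Leukocyte markers summed to 12.3 ± 1.44 CPM in siC and 8.21 ± 2.66 CPM in siFGF13 (two-sided exact permutation p = 0.1), of which CD14 made up 91.1%. Endothelial markers summed to 44.9 ± 7.29 and 34.8 ± 7.16 CPM (exact p = 0.3), 90.5% of it EGFL7. Lung epithelium markers summed to 24.7 ± 2.77 and 27.4 ± 1.26 CPM (exact p = 0.3), and kidney and liver markers to 2.92 ± 0.367 and 3.57 ± 0.188 CPM (exact p = 0.1, n = 3 per group throughout).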

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

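Both replicate 1 libraries left out, the block with a length and GC correction, the recovered reads and fry with the block were chosen after the data were seen. FGF13 stayed lower and past the threshold in each alternative run. The counts of higher and lower genes stayed within 1.5 times of 1182 and 1446 with RLE or upper-quartile scaling, either filter, DESeq2, limma-voom and both replicate 1 libraries left out. For the counts of genes higher in siFGF13 and genes lower in siFGF13, the values were 140 and 274 at an adjusted p under 0.01 and 157 and 369 with glmTreat, which are stricter by construction. With the replicate block they were 1821 and 2244, and with the block and the length and GC correction 2392 and 2109. The median log2 fold change of all tested genes was -0.0095 with the block and 0.032 with the block and correction. This shift favours higher calls. Leaving out 1 library gave 149 to 1407 higher and 275 to 1662 lower, with smaller counts in 4 of the 6 fits and larger sums in the other 2, for reasons that were not tested. Camera called 16 to 21 lists across its settings with the preset correlation, but 0 with an estimated one, where 1 list (ATF4) had an unadjusted p under 0.05. Fry called 17 lists, 14 of them among the 18 that camera called. With the replicate block it called 4 (ATF4 targets, NF-kB targets, epithelial genes and RNA interference genes). The block thus ended the other fry calls, among them ribosome production (0.0291 to 0.119), heat shock (0.0257 to 0.0894) and S phase (0.0257 to 0.0881). It also leaves fewer residual degrees of freedom, which by itself can raise fry p-values. With the same block, camera called 18 lists with the preset correlation, and edgeR called more genes than without it. In edgeR and in camera with the preset correlation, the replicate block changed the calls of NOP56, AKR1B10, HIST1H1C, MTRNR2L6, the NRF2 list and the RNA interference list, and no other call of a named gene or list in those tests. The ERK and epithelial lists passed camera without both replicate 1 libraries (0.0214 and 0.0190). Of 129 genes that passed and were named by the rule or chosen after their values were seen, 63 passed in each of the 6 fits with a library left out and 59 lost the call without siFGF13 replicate 1.

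Results that changed sign had not passed the test, and the cause was not tested. Without both replicate 1 libraries, the log2 fold change of CDKN1A was -0.0572, the log2 fold change of ATF4 -0.0353, the log2 fold change of FGF11 0.0233 and the log2 fold change of FGF14 0.00621. ATF4 was at -0.00695 with a mean of at least 5 CPM. With the replicate block with length and GC correction MDM2 was at 0.0422 (the log2 fold change of MDM2 was otherwise below 0) and FGF14 at 0.0324. With 1 library left out, values ran from -0.123 (without siC replicate 1) to 0.230 for CDKN1A, and for the log2 fold change of HSPA5 from -0.255 to 0.0260 (without siC replicate 1). They ran from -0.0689 (without siC replicate 1) to 0.0658 for ATF4, from -0.257 to 0.0770 (without siFGF13 replicate 1) for FGF11, and for the log2 fold change of FGF2 from -0.0124 (without siC replicate 2) to 0.111.

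The mean log2 change of list glycolysis_hypoxia was -0.163 with upper-quartile factors, -0.162 with fry, -0.112 with a mean of at least 5 CPM or the block with correction, -0.136 with limma-voom and -0.189 without both replicate 1 libraries. It was -0.244 (without siC replicate 1) to -0.00923 (without siC replicate 3) with 1 library left out. Its sign counts as turned because camera and the mean disagreed. The mean log2 change of list cholesterol_biosynthesis was -0.0411 with the block, 0.0558 without both replicate 1 libraries and -0.00223 with the block and correction, and ran from -0.126 to 0.0424 (without siFGF13 replicate 1) with 1 library left out. The mean log2 change of list MAPK_early_response (ERK) was 0.0844 with no filter, -0.00194 without siC replicate 3, -0.184 without siC replicate 1 and -0.208 without both replicate 1 libraries. The mean log2 change of list interferon_response was 0.0108 with no filter, 0.0280 without both replicate 1 libraries, 0.0283 with the block and correction, and 0.00688, 0.0216 and 0.0263 without siC replicate 1, siC replicate 2 and siFGF13 replicate 1. The mean log2 change of list apoptosis_regulators ran from -0.112 to -0.0536 with 1 library left out.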

Other observations

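TXNIP, ARRDC4, GADD45A, HSPA13, CCND1, CCNE1, DNAJB1 and the MTRNR2L family were chosen after their values were seen, the TMEM family after the list results were seen, and the fits without both replicate 1 libraries and with the block and correction after the data were seen. TXNIP, an arrestin known to restrain glucose uptake, fell from 207 ± 58.0 to 52.8 ± 11.4 CPM (log2 fold change -1.97 ± 0.21, edgeR adjusted p = 0.00193), and its relative ARRDC4 fell from 20.5 ± 2.23 to 11.1 ± 0.42 CPM (adjusted p = 0.00481). The growth arrest gene GADD45A fell 1.89-fold (adjusted p = 0.00186), and HSPA13, a HSP70 relative of the microsomes, fell 2.08-fold (adjusted p = 0.00648) while the cytosolic HSP70 genes rose. DNAJB1, the co-chaperone of the inducible HSP70, rose 2.06-fold (adjusted p = 0.00641).

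CCNE1, a cyclin of entry into S phase, rose from 9.31 ± 0.623 to 17.3 ± 2.83 CPM (log2 fold change 0.89, edgeR adjusted p = 0.00737) and the cyclin CCND1 from 55.2 ± 13.2 to 103 ± 13.2 CPM (0.89, adjusted p = 0.0107), though the CCND1 call ended without siFGF13 replicate 1 (0.0574). Of 7 tested MTRNR2L genes, nuclear copies of mitochondrial ribosomal RNA sequence, 6 were lower and none higher, with log2 fold changes of -1.43 to -0.88 and a median of -1.18. The copies are near-identical to each other and to the mitochondrial transcript, so these reads cannot be assigned to 1 gene. MTRNR2L6 missed the threshold (0.0620) and passed with the replicate block (0.0294), and MTRNR2L2 lost its call without siFGF13 replicate 1 (0.0596).

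The 6 libraries can be split into 3 and 3 in 10 ways, and 1 of the 10 splits, the real one, gave as many as 2628 genes in edgeR. The highest of the other splits gave 0 adjusted calls, and 34 to 529 genes at an unadjusted p under 0.05 against 4918 for the real split. The other splits that part the 3 replicate pairs gave 40, 126 and 34 genes at that level. With 10 splits a share under 0.05 cannot be reached. Each of the other splits also mixes siC and siFGF13 libraries on both sides. The difference between the groups then adds to the spread within each side and lowers the calls, so their low counts were to be foreseen.

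The lower level of the ATF4 list was tested against 2 technical explanations. After correction for transcript length and GC content the list mean was -1.03, and the mean closest to 0 with 1 library left out was -1.02, which argue against a length or GC bias and against a single library as the whole cause. Other regulators upstream of these genes stay open. The values may reflect lower activity of the ATF4 pathway although the ATF4 transcript itself did not pass the test, a hypothesis that protein levels, not measured here, would test. No untransfected cells are analysed here, so a stress response raised by the control siRNAs and one lowered by the FGF13 siRNAs cannot be separated.

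The higher level of the HSP70 genes and of the ribosome production list was tested in the same way. The 27 heat shock genes outside the near-identical HSP70 copies, HSPA8 among them, had a mean log2 change of 0.48, with 18 higher and none lower. The 95% bootstrap interval of 0.338 to 0.655 treats genes as independent, although the estimated correlation in the whole list was 0.468. It does not measure the spread between libraries. The rise was thus not confined to the near-identical copies, but how reads were split among those copies was not tested. HSPA8 kept an adjusted p of at most 0.0206 with 1 library left out. The ribosome production list had a mean of 0.38 after the length and GC correction, where the median of all tested genes was 0.03. Its mean was 0.26 without both replicate 1 libraries. These values argue against a length or GC bias and against the replicate 1 libraries as the whole cause. An effect of the siRNA pool other than through FGF13 stays open for these genes, since 1 pool was used. So does a difference in RNA selection or quality. The replication-dependent histones (mean log2 change 0.69 over 6 tested members) are a possible sign of it only if their reads came from messages without a tail. As the S-phase list was also higher, the histones cannot separate RNA selection or quality from a change in the cell cycle.

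A search for 7-mers in 3' untranslated regions that go with lower expression met the condition set for an off-target effect, but no siRNA seed was matched, since the pool sequences are not given in the sources used here. Among 15642 7-mers in 11772 genes, TATTTAT went most strongly with lower expression (t = -6.43, slope -0.0576 in log2), past the lowest of 100 permutations (-5.19) and past the strongest 7-mer that went with higher expression (t = 5.75, GCCGAGG), which was itself past the permutations (4.94). In all, 3 7-mers passed the permutations on the lower side and 5 on the higher side, where seeds of this kind are not expected to act. Most of these overlap in sequence, so they do not count as separate motifs. ATATTTA, TATTTAT and TTTATAT do so on the lower side, and GAGGCCG, AGGCCGA, GGCCGAG and GCCGAGG on the higher side. An off-target effect may account for part of the lower genes, but the AU-rich 7-mer TATTTAT also resembles elements that destabilise inflammatory messages. No TATTTAT site was found for UNC5B. As the siRNA seeds are unknown, this cannot tell whether UNC5B is an off-target of the pool. The 166 genes named TMEM had a mean log2 change of -0.22 (blocked -0.21), with 34 lower and 5 higher, below random sets matched on expression (95% of 10000 sets between -0.11 and 0.01, permutation test p = 0.0002, the smallest it can give, genes treated as independent). Lower transcripts of membrane proteins as a class, from handling or biology, may thus explain part of the lower values of the endoplasmic reticulum, lysosome and matrix lists.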
